A study of Sus scrofa with 12 samples.

How the data were processed

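RNA was measured by sequencing in 12 libraries of cultured pig (Sus scrofa) aortic valve interstitial cells, the fibroblast-like cells of the valve leaflet. Per the labels' protocols, cells were grown on glass in DMEM for up to 12 days, depending on when each stage was seen, and 500 ng of DNA-free total RNA per library went into the Illumina TruSeq Stranded mRNA kit. The labels put 3 biological replicates into each of 4 groups, which are Stage 1 (day 5), Stage 2 (day 8), Stage 3 with DMSO and Stage 3 with KPT. The day of growth of each Stage 3 library, the dose and the time of exposure to KPT are not given in the sources used here. Nothing in the labels says whether the replicates came from separate animals, so the p-values measure the spread between cultures of unstated origin.

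Reads were aligned with TopHat2 2.1.0, per the submitters' processing notes. The counter, the genome build and the annotation release are not given in the sources used here. The authors deposited RPKM values (reads scaled to exon length and to a library total) for 22861 genes and 189618 exons, with Ensembl pig gene IDs and coordinates. Gene symbols came from the gene table for 15203 genes, from a table of IDs and symbols for 1715 more and from the Entrez number for 627 more. No row named COL1A1, ALPL or CDKN1A was found, so these genes of the fixed panel were not analysed here. The counting was not stated to use strand, so reads of overlapping or antisense genes may have been split either way, as may those of near-identical copies such as ribosomal protein pseudogenes and the paired IDs of NDUFA4L2, SESN2, GZMA, ADAMTS1, BUB1B and RUNX2.

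The deposited RPKM values were multiplied by the union exon length and by a whole-number library total. This gave whole reads for 100% of gene values and of exon values in every library, within 0.0001 of a read. The library totals recovered in this way were 13188023 to 24724019. The reads summed over genes were 23287593 to 43293744 per library, 1.751 to 1.813 times the library total, and the reason for that ratio is not given in the sources used here. The recovered reads gave the depth behind each value and counting intervals, which cover counting error only, and the added limma-voom fit. The intervals treat every read as independent, which that ratio leaves uncertain, so they may be too narrow.

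The main test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 1). All 12 libraries entered one fit with a coefficient per group, moderated with an expression trend, and the 4 comparisons were contrasts of that fit. A gene was tested if its RPKM was at least 1 in at least 3 libraries, which left 13046 genes, of which 10779 had a symbol. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. Values after ± are standard deviations over 3 libraries, and SE marks the standard error of a log2 fold change.

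Gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry. Lists with fewer than 5 tested members were not tested. A symbol held by several IDs was represented in the lists and the fixed panel by the ID with the highest mean RPKM. The lists covered osteogenic and mineralisation genes, calcification inhibitors, contractile genes, collagens and elastic fibres, proteoglycans, matrix proteolysis, S phase, mitosis, p53 targets, nuclear transport, the C/EBP family, respiratory chain genes of nuclear and of mitochondrial origin, glycolysis, hypoxia, NF-kB and cytokines, interferon response, complement, the unfolded protein and integrated stress response, cholesterol synthesis, NRF2 targets, heat shock, BMP and TGF-beta targets, Notch, Wnt, autophagy and lysosome, cytoplasmic ribosomal proteins, markers of endothelial cells, leukocytes, cardiomyocytes, adipocytes, epithelial and erythroid cells, and sex-linked genes.

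Genes are named by a rule fixed before the data were examined. It takes the largest rises and falls among called genes with a symbol and non-overlapping replicates, up to 2 called members in each direction of each list past the threshold, and a fixed panel that includes XPO1, RUNX2, SPP1, BGLAP, MGP, SOX9, ACTA2, CEBPB and MKI67. Some genes that the rule takes are left out for length. The alternatives were pseudocounts of 0.1 and 0.5, no filter, a minimum RPKM of 5, rescaling by the median ratio, quantile normalization, no trend, a fit of the 2 groups alone, library quality weights, a replicate block and leaving out each library. Added after seeing the data were limma-voom on the recovered reads, a minimum of 10 recovered reads, leaving out replicate 1 of every group, library totals without the 100 most abundant genes or other numbers of them, the count of opposite changes at successive stages after median-ratio rescaling or quantile normalization, simulations on those scales, splits of the libraries that 2 comparisons share, and fry after median-ratio rescaling or quantile normalization.

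The fits were tested on simulated reads with 200 changed genes per comparison. For Stage 3+KPT against Stage 3+DMSO, run on 12918 genes, 80.6% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 10 of 12678 unchanged genes were called. For Stage 2 against Stage 1, run on 13066 genes, the recovered shares were 83.6%, 97% and 100%. For Stage 3+DMSO against Stage 2, run on 12972 genes, they were 89.6%, 89.6% and 98.5%, and for Stage 3+DMSO against Stage 1, run on 12986 genes, 80.6%, 97% and 98.5%. Genes were simulated independently, with the same dispersion of 0.0039 in every library. Replicate spread in the real libraries differed between groups and genes of some lists varied together, so these values may be optimistic. Scripts in Python with pandas recovered the reads and compared the RPKM of the last and the first exon of each gene with at least 5 exons.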

Results

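Messenger RNA was profiled in porcine aortic valve interstitial cells, which form and maintain the matrix of the valve leaflet, at successive stages of calcification in culture and after KPT. The 12 libraries fell into 4 groups of 3, which were Stage 1 (day 5), Stage 2 (day 8), Stage 3 with the solvent DMSO and Stage 3 with KPT. The labels give no fuller name for KPT. Compounds with KPT code names are known as inhibitors of XPO1, the nuclear export receptor, and which of them was used is not stated. Library totals inferred from the RPKM values ranged from 13188023 to 24724019, in a unit that is not given, and 13046 genes were expressed highly enough to be tested. Replicates of a group correlated across genes with r from 0.985 to 0.994, and every pair differed by more than counting noise (chi-square per degree of freedom from 5.82 to 46.2).

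KPT-treated libraries stood apart from all others on the first principal component, which held 59.4% of the variance. The second component (17.0%) ordered the untreated groups from Stage 1 through Stage 2 to Stage 3+DMSO. Of the markers of other cell types, the 7 tested endothelial genes did not pass the threshold as a list in any comparison (camera adjusted p from 0.508 to 0.916). Too few leukocyte (4), cardiomyocyte (3), adipocyte (1) and sex-linked (1) genes were expressed to test, and no epithelial or erythroid gene passed the expression filter (0 of each).

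**Figure D1:**
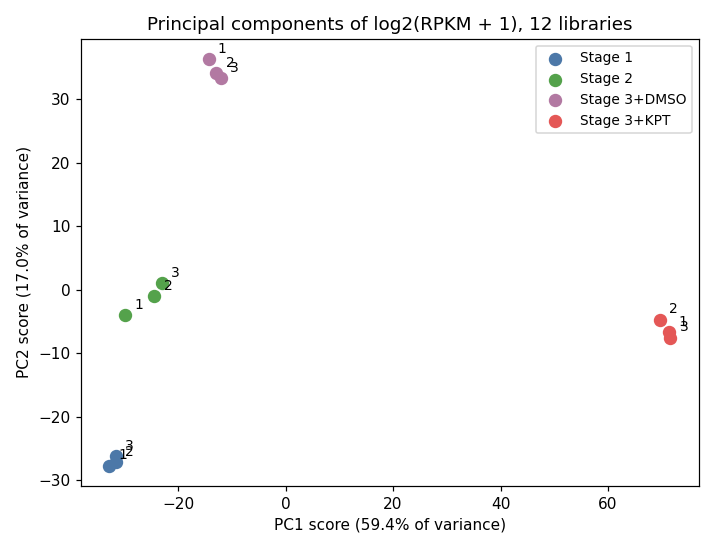
Scores of the 12 libraries on the first and second principal components of log2(RPKM + 1), in arbitrary units, with colours for the 4 groups and the replicate number beside each point. The 3 KPT libraries lie alone at high values of the first component (59.4% of the variance), and the second (17.0%) separates the 3 other groups.

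Stage 2 was compared with Stage 1 to ask how transcript levels differ between day 5 and day 8. Mitosis genes fell at Stage 2 in all 20 tested members, with a median log2 fold change of -1.33 (camera adjusted p = 0.0774 with an estimated correlation). MKI67, a marker of cycling cells, went from 12.4 ± 1.52 RPKM at Stage 1 to 4.43 ± 0.435 at Stage 2 (SD, n = 3; log2 fold change -1.30, limma adjusted p = 7.25e-06). Calcification inhibitors rose in 8 of 9 members, and collagen, elastic fibre and cross-linking genes in 15 of 26 (adjusted p = 0.0377 and 0.109 with an estimated correlation). MGP, matrix Gla protein, an inhibitor of vascular calcification, went from 548 ± 29.8 to 1589 ± 60.1 RPKM (log2 fold change 1.53, SE 0.08, adjusted p = 1.98e-07).

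The fall of the mitosis list (camera adjusted p = 1.04e-11, and adjusted p = 0.0774 with an estimated correlation) included AURKB, a mitotic kinase, which went from 23.0 ± 0.888 to 8.96 ± 0.868 RPKM, and KIF20A, a mitotic kinesin, from 46.1 ± 3.88 to 15.7 ± 1.32. All 20 members also passed adjusted over the list alone. Of 18 S phase genes 13 fell and none rose (0), or 14 adjusted over the list alone (adjusted p = 2.59e-04, and adjusted p = 0.477 with an estimated correlation), among them UHRF1 and CDC45 (log2 fold changes -1.09 and -0.95). Nuclear transport genes fell in 20 of 30 members, a count of 20 also adjusted over the list alone (adjusted p = 6.49e-06, and 0.0493 as the adjusted p with an estimated correlation). The import receptor KPNB1 and the exporter XPO5 changed by -0.54 and -0.57. XPO1 itself had 33.0 ± 1.99 RPKM at Stage 1 and 26.8 ± 6.29 at Stage 2, a difference that did not pass the threshold (adjusted p = 0.135).

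Calcification inhibitors rose in 8 of 9 members, likewise 8 adjusted over the list alone (adjusted p = 1.44e-06, and adjusted p = 0.0377 with an estimated correlation). Beside MGP, GAS6, a vitamin K-dependent ligand, rose from 23.7 ± 0.539 to 74.8 ± 1.19 RPKM. Collagen, elastic fibre and cross-linking genes rose in 15 of 26 members, or 16 adjusted over the list alone (adjusted p = 1.10e-07, and adjusted p = 0.109 with an estimated correlation). ELN, which encodes elastin, went from 8.31 ± 0.438 to 40.1 ± 6.06 RPKM, and LOXL1, which cross-links elastin, changed by 1.12. Proteoglycan and chondrogenic genes rose in 11 of 16 members, and adjusted over the list alone 11 rose and 1 fell (adjusted p = 2.91e-06, and adjusted p = 0.0493 with an estimated correlation). FMOD, a collagen-binding proteoglycan, went from 3167 ± 41.5 to 6047 ± 66.2 RPKM, and SOX9, a chondrogenic transcription factor, rose by 0.79 (SE 0.07).

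Autophagy and lysosome genes rose in 14 of 20 members, with GAA and GABARAPL1 both up by 0.68 (adjusted p = 7.41e-06, and adjusted p = 0.147 with an estimated correlation). Of 23 p53 targets 9 rose and 2 fell, with MDM2 up by 0.82 and PLK3 changed by -1.27 (adjusted p = 0.0076, and adjusted p = 0.152 with an estimated correlation). NRF2 targets rose in 8 of 16 and fell in 2 (adjusted p = 0.0076, and adjusted p = 0.281 with an estimated correlation), with the ferritin gene FTL up by 0.68. The nuclear-encoded respiratory chain list moved up by a median of only 0.10, with 7 of 36 members called higher and 1 lower, or 13 and 0 after median-ratio rescaling (adjusted p = 0.0124, and adjusted p = 0.642 with an estimated correlation). Mitochondrially encoded genes had 7 of 13 members lower (median -0.43, adjusted p = 0.0144, and adjusted p = 0.659 with an estimated correlation). This call was lost without Stage 2 replicate 1 (adjusted p = 0.0907) and without replicate 1 of every group (0.0698). Complement and antigen presentation genes had 4 of 14 members higher, including C7 (2.32), at adjusted p = 0.0223, with an adjusted p = 0.659 with an estimated correlation. That list too was lost without Stage 2 replicate 1 (adjusted p = 0.0935), and also under quantile normalization (0.0606) and at a minimum RPKM of 5 (0.0559).

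Adjusted over the list alone, the counts of higher and lower genes at Stage 2 were 14 and 0 for autophagy, 9 and 4 for p53 targets, 9 and 2 for NRF2 targets, 4 and 0 for the nuclear-encoded and 0 and 7 for the mitochondrially encoded respiratory chain, and 4 and 0 for complement. Osteogenic genes did not pass as a list (adjusted p = 0.0806), with 5 of 13 members higher and 2 lower, the same numbers adjusted over the list alone. The osteoblast transcription factor RUNX2 fell from 20.5 ± 0.653 to 14.4 ± 0.189 RPKM. Here and below this is the ID of the RUNX2 pair with the higher mean RPKM, and the other ID is not described. CEBPB fell by 0.94, ACTA2 (smooth muscle actin) fell by 0.54, and SPP1 (osteopontin) had 17.8 ± 2.71 and 15.8 ± 0.487 RPKM (adjusted p = 0.738). BGLAP (osteocalcin) was lower at Stage 2 (adjusted p = 0.00883) but had only 52 reads over the 3 Stage 1 libraries and 11 over the Stage 2 libraries, and it did not pass without replicate 1 of every group (adjusted p = 0.0923). Wnt genes and cytoplasmic ribosomal proteins did not pass as lists (adjusted p = 0.0609 and 0.0643), but did in 2 and 7 of 19 alternatives respectively, among them leaving out Stage 2 replicate 3 for Wnt (0.0348) and quantile normalization for ribosomal proteins (6.32e-04). Osteogenic genes passed in the limma-voom fit alone (0.0484).

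The largest rises at Stage 2 were those of TXNIP, a thioredoxin-binding protein (0.640 ± 0.114 to 29.2 ± 9.77 RPKM, log2 fold change 4.15), the acute-phase gene SAA3 (4.06) and PLXDC1 (3.63). TMEM100, C1QTNF3, INMT and MATN2 rose by 3.44, 2.80, 2.41 and 2.37. A further large rise (2.86) was that of an ID named TNFSF10 in the gene table and GHSR in the table of IDs, so its identity is uncertain. The largest falls with more than a few reads were those of the hormone gene SST (-3.40), the collagenase MMP1 (77.6 ± 4.86 to 9.53 ± 1.41 RPKM, -2.91), the deiodinase DIO2 (-2.36) and the hyaluronan-binding CEMIP (-2.16). In total 5308 genes changed, 2127 higher and 3181 lower at Stage 2, of which 247 and 311 by at least 2-fold. After median-ratio rescaling 2583 were higher and 2689 lower, or 49.0% higher against 40.1% as deposited. That rescaling centres the fold changes of all genes near no change, so it evens out these counts largely by design. The groups did not overlap for 52.5% of tested genes, where chance gives 10%. The last exon of a gene held more reads relative to the first at Stage 1 (median log2 ratio 0.345 ± 0.015) than at Stage 2 (0.279 ± 0.028; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows).

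Stage 3 with DMSO was compared with Stage 2 for the later step of calcification, in which the solvent also differs. Genes of glycolysis, the hypoxia response and cholesterol synthesis fell (adjusted p = 0.102, 0.0101 and 0.0299 with an estimated correlation). LDHA, lactate dehydrogenase A, went from 2809 ± 40.2 RPKM at Stage 2 to 1092 ± 82.6 (SD, n = 3; log2 fold change -1.36, adjusted p = 2.43e-08). Mitosis and S phase genes rose, and so did genes of the integrated stress response (adjusted p = 0.201, 0.484 and 0.0325 with an estimated correlation). MGP rose further to 4378 ± 532 RPKM (1.46, SE 0.08, adjusted p = 1.06e-07).

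Of 19 glycolysis genes 16 fell and 1 rose (LDHB), and adjusted over the list alone 17 fell (adjusted p = 1.37e-15, and adjusted p = 0.102 with an estimated correlation). ALDOC, an aldolase, went from 320.8 ± 23.4 to 77.0 ± 7.64 RPKM. Cholesterol synthesis genes fell in 18 of 20 members with PMVK the 1 that rose, the same counts adjusted over the list alone (adjusted p = 1.37e-15, and adjusted p = 0.0299 with an estimated correlation). HMGCS1, an early enzyme of the pathway, went from 250.9 ± 24.9 to 77.1 ± 3.18 RPKM, and IDI1 fell by 1.35. Hypoxia response genes fell in 12 of 16 members and rose in 2, also adjusted over the list alone (adjusted p = 4.11e-07, and adjusted p = 0.0101 with an estimated correlation), with BNIP3 and PDK1 changed by -1.47 and -0.99 and STC2 up by 1.19.

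Mitosis genes rose in 19 of 20 members (median 1.00, adjusted p = 2.64e-06, and adjusted p = 0.201 with an estimated correlation) and S phase genes in 16 of 18 (median 0.92, adjusted p = 2.17e-04, and adjusted p = 0.484 with an estimated correlation), with the same counts adjusted over the list alone. PCNA, the replication clamp, went from 21.3 ± 3.53 to 59.3 ± 8.95 RPKM, TOP2A from 9.75 ± 1.05 to 32.7 ± 7.82, and MKI67 from 4.43 ± 0.435 to 9.73 ± 1.20. Of 22 unfolded protein and integrated stress response genes 15 rose and 1 fell (adjusted p = 4.49e-04, and adjusted p = 0.0325 with an estimated correlation), again the same adjusted over the list alone. PSAT1, of serine synthesis, rose from 94.6 ± 7.52 to 599.7 ± 84.5 RPKM, ASNS, asparagine synthetase, from 69.7 ± 3.66 to 255.8 ± 23.0, while SHMT2 fell by 0.50.

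Contractile and activated-cell genes fell in 10 of 18 members and rose in 2, the same adjusted over the list alone (adjusted p = 6.17e-06, and adjusted p = 0.0705 with an estimated correlation). DES, which encodes desmin, went from 126.0 ± 25.2 to 6.17 ± 4.90 RPKM and ACTG2, a smooth muscle actin, from 190.1 ± 43.5 to 17.6 ± 5.74, while POSTN, the matricellular periostin, rose from 356.2 ± 79.5 to 1068 ± 130. Collagen and cross-linking genes had 12 of 26 members lower and 6 higher, or 13 and 6 adjusted over the list alone (adjusted p = 0.00129, and adjusted p = 0.339 with an estimated correlation), with LOX changed by -0.65 and COL14A1 by 1.28. That call was lost under quantile normalization (adjusted p = 0.573). BMP and TGF-beta targets had 6 of 15 members lower and 3 higher, unchanged in number adjusted over the list alone (adjusted p = 0.0292, and adjusted p = 0.189 with an estimated correlation), with ID1 down and BAMBI up (-0.88 and 0.84). The BMP list was not past the threshold in 4 of 19 alternatives, which were quantile normalization (adjusted p = 0.0828), no filter (0.0527) and leaving out Stage 2 replicate 1 (0.0542) or Stage 3+DMSO replicate 3 (0.0547).

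Nuclear transport genes were higher in 17 of 30 members and lower in none (0), or 19 adjusted over the list alone (adjusted p = 0.021, and adjusted p = 0.221 with an estimated correlation), but after median-ratio rescaling only 8 were higher and 2 lower (adjusted p = 0.160), and the list was also lost under quantile normalization (0.0821). Autophagy and lysosome genes were higher in 12 of 20 and lower in 2, or 13 and 2 adjusted over the list alone (adjusted p = 0.0292, and adjusted p = 0.484 with an estimated correlation). CTSB, a lysosomal protease, went from 1310 ± 28.0 to 2513 ± 142 RPKM. The autophagy call was lost under rescaling (adjusted p = 0.0600) and without Stage 3+DMSO replicate 2 (adjusted p = 0.0505). Cytoplasmic ribosomal proteins passed as a list (adjusted p = 0.0292, and adjusted p = 0.852 with an estimated correlation) on a median of -0.04 with 1 of 35 members called in each direction and 0 adjusted over the list alone. After median-ratio rescaling 17 were lower and 0 higher (median -0.20), and without Stage 3+DMSO replicate 3, under quantile normalization and without a filter their adjusted p was 0.671, 0.986 and 0.0527. Mitochondrially encoded genes did not pass (adjusted p = 0.057), but did in 6 of 19 alternatives, among them leaving out Stage 2 replicate 1 (0.00565) or Stage 3+DMSO replicate 1 (0.0188) and library quality weights (0.00681).

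Of the fixed panel, RUNX2 fell by 0.65 and ACTA2 by 0.57, while CEBPB (adjusted p = 0.716) and XPO1 (adjusted p = 0.474) did not pass the threshold. SOX9 was higher by 0.21 (adjusted p = 0.0333), a call lost in 8 of 19 alternatives, among them median-ratio rescaling (0.05, adjusted p = 0.646), quantile normalization (0.637) and leaving out any 1 Stage 2 library (0.0582 to 0.0727). XPO1 was lower in 3 of 19, namely without Stage 2 replicate 1 (-0.35, adjusted p = 0.0451), with library quality weights (0.0239) and without replicate 1 of every group (0.0264). SPP1 hung on 1 library. It was 10.1, 30.5 and 35.8 RPKM in Stage 3+DMSO replicates 1, 2 and 3, and its rise from 15.8 ± 0.487 did not pass with all of them (0.48, adjusted p = 0.249) but did without replicate 1 (1.02, adjusted p = 3.60e-05). The largest rises were those of FAM180A (3.02), RGS4 (2.79), PSAT1 (2.65), COMP, a cartilage matrix protein (2.49), ATF5 (2.48) and the transporter ABCB1 (2.40). FABP3, SLC6A6, MYBPH and GALNT15 fell by 2.69, 2.42, 2.32 and 2.28, behind DES and ACTG2 (-4.34 and -3.39).

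In total 5755 genes changed, 4309 higher and 1446 lower in Stage 3+DMSO, with 476 and 152 by at least 2-fold. Thus 74.9% of the called genes were higher as deposited, against 50.8% of 5168 called genes after median-ratio rescaling. That rescaling evens out the counts largely by design, and it shifted the log2 fold change of all genes by a median of -0.16. Relative to that shift the medians of the glycolysis, cholesterol and hypoxia lists were -0.96, -0.87 and -0.66, and those of mitosis, S phase and the stress response 0.86, 0.77 and 0.44. Groups did not overlap for 51.1% of genes (10% by chance).

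Stage 3+DMSO was also compared with Stage 1, over the whole course. PLXDC1 rose from 1.35 ± 0.138 to 114.0 ± 25.6 RPKM (log2 fold change 5.59, adjusted p = 8.64e-10), and MGP from 548 ± 29.8 to 4378 ± 532 (2.99, SE 0.08, adjusted p = 5.90e-10). VEGFA, the angiogenic factor, fell from 592.5 ± 59.8 to 139.5 ± 12.6 RPKM, and RUNX2 from 20.5 ± 0.653 to 8.88 ± 1.15. Contractile genes, glycolysis and cholesterol synthesis were lower (adjusted p = 0.204, 0.195 and 0.0487 with an estimated correlation), and calcification inhibitors and lysosomal genes higher (adjusted p = 0.113 and 0.195 with an estimated correlation).

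Calcification inhibitors rose in 7 of 9 members and fell in 1 (adjusted p = 0.00218, and adjusted p = 0.113 with an estimated correlation), with GAS6 up by 2.48. Autophagy and lysosome genes rose in 14 of 20 (adjusted p = 2.04e-05, and adjusted p = 0.195 with an estimated correlation), among them SQSTM1 (1.12) and CTSB (1.33). The stress response list rose in 13 of 22 and fell in 3 (adjusted p = 0.0115, and adjusted p = 0.113 with an estimated correlation). Cholesterol synthesis fell in 19 of 20, glycolysis in 16 of 19 and hypoxia genes in 11 of 16 (adjusted p = 6.16e-13, 1.16e-10 and 1.75e-05, and adjusted p = 0.0487, 0.195 and 0.0249 with an estimated correlation), with 1 member of each higher. INSIG1, of sterol control, changed by -1.44. Contractile genes fell in 10 of 18 and rose in 5 (adjusted p = 0.00269, and adjusted p = 0.204 with an estimated correlation). After median-ratio rescaling 10 fell and 2 rose. ACTA2 went from 18443 ± 574 to 8571 ± 1149 RPKM, TPM2 fell by 1.04 and POSTN rose by 2.73.

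Mitosis genes remained lower than at Stage 1 as a list, with 8 of 20 called (adjusted p = 0.00218, and adjusted p = 0.377 with an estimated correlation), CCNB1 and CDC20 by 0.83 and 0.66. Mitochondrially encoded genes fell in 9 of 13 members (adjusted p = 6.59e-04, and adjusted p = 0.493 with an estimated correlation), with ND5 and COX1 changed by -1.23 and -0.92, and cytoplasmic ribosomal proteins in 12 of 35 (median -0.14, adjusted p = 2.83e-04, and adjusted p = 0.545 with an estimated correlation). After median-ratio rescaling 26 ribosomal proteins were lower (median -0.25). Adjusted over the list alone, the higher and lower counts were 7 and 1 for calcification inhibitors, 14 and 0 for autophagy, 14 and 3 for the stress response, 1 and 19 for cholesterol, 1 and 16 for glycolysis, 1 and 11 for hypoxia, 5 and 10 for contractile genes, 0 and 8 for mitosis, 0 and 9 for mitochondrially encoded genes and 0 and 5 for ribosomal proteins. CEBPB fell by 0.99 and SOX9 rose by 1.00. XPO1 was lower by 0.47 (adjusted p = 0.0296), a call lost in 5 of 19 alternatives (adjusted p from 0.0539 to 0.0906), of which 4 left out 1 library and 1 had no filter. SPP1 did not pass (adjusted p = 0.424), but without Stage 3+DMSO replicate 1 it was higher by 0.86 (adjusted p = 9.03e-05). MKI67 was lower by a log2 fold change of -0.32 (adjusted p = 0.0415), a call lost in 9 of 19 alternatives (adjusted p from 0.0530 to 0.160), of which 4 kept all libraries.

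Osteogenic genes did not pass as a list over the course (adjusted p = 0.157, with 8 of 13 members higher and 1 lower, or 8 and 2 adjusted over the list alone), but did without Stage 3+DMSO replicate 1 (0.0355), as did S phase genes (0.47 with all libraries and 0.0261 without it). Targets of p53, complement genes and proteoglycans each had an adjusted p of 0.0531. They passed in 4, 7 and 5 of 19 alternatives, among them quantile normalization (0.0460, 0.0286 and 0.0126) and leaving out Stage 3+DMSO replicate 2 (0.0308, 0.0138 and 0.0267). Nuclear transport genes did not pass either (camera adjusted p = 0.0644), with 4 of 30 members higher and 8 lower. They passed as lower after median-ratio rescaling (0.0176, 1 higher and 12 lower) and quantile normalization (0.0370, 1 and 11).

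Other large rises over the course were those of MATN2 (3.51), S100A1 (3.43), SAA3 (3.40) and TMEM100 (3.39), and large falls were those of ACTG2 (-3.55), MMP1 (-3.10) and GZMA, present as a pair of IDs (-3.42 and -3.09). Among 6226 changed genes 3975 were higher and 2251 lower, and 668 and 297 changed by at least 2-fold. The higher share was 63.8% as deposited and 48.4% of 6122 after median-ratio rescaling, which shifted the median by -0.11 and evens out the counts largely by design. Groups did not overlap for 59.0% of genes, against 10% by chance. The last exon of a gene held fewer reads relative to the first in Stage 3+DMSO (0.271 ± 0.012) than at Stage 1 (0.345 ± 0.015; exact permutation test, two-sided p = 0.1, the smallest possible).

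**Figure D2:**
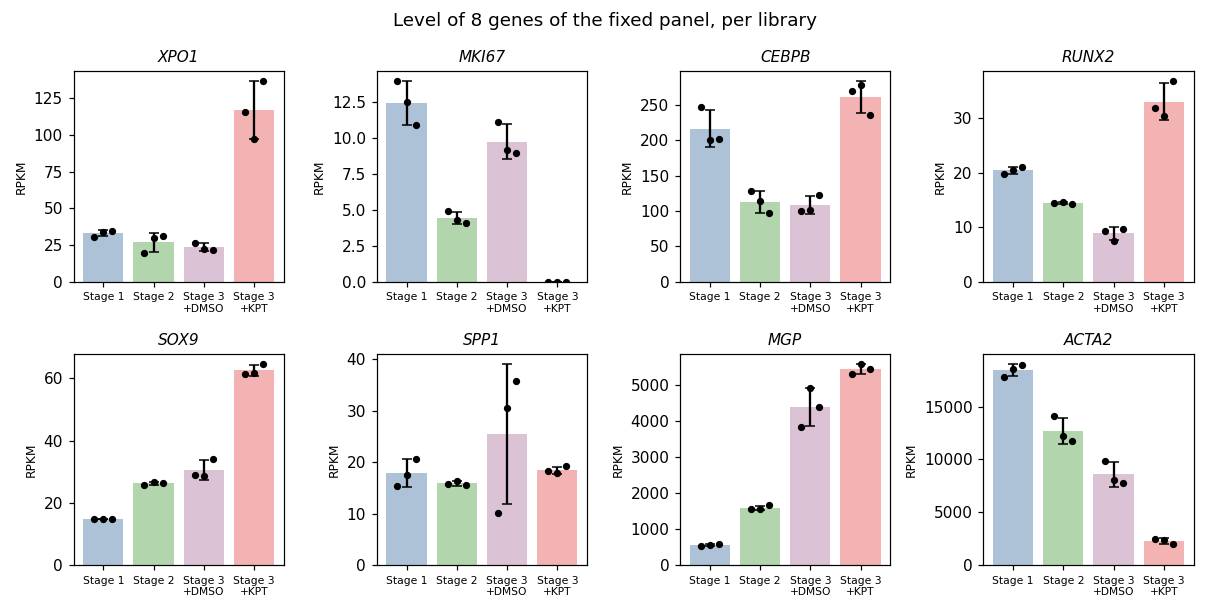
RPKM of 8 genes of the fixed panel in each of the 12 libraries (black points), with bars for the mean of the 3 libraries of a group and error bars for their SD. XPO1, RUNX2 and CEBPB are highest and ACTA2 lowest with KPT, MKI67 is near 0 there, MGP is higher in each later group, and SPP1 spreads from 10.1 to 35.8 RPKM within Stage 3+DMSO.

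KPT was compared with DMSO at Stage 3 to ask how transcript levels differed with the compound. The day of growth of each Stage 3 library is not given, so a difference in culture time cannot be told apart from the compound. Mitosis genes, contractile genes and most collagen and cross-linking genes fell (adjusted p = 0.0481, 0.0481 and 0.218 with an estimated correlation). NF-kB and cytokine genes, p53 targets and XPO1 itself rose (adjusted p = 0.0481 for both lists with an estimated correlation). XPO1 (chromosome 3, 84163385 to 84182474, in a genome build not given in the sources used here) went from 23.7 ± 2.69 to 116.7 ± 19.8 RPKM (SD, n = 3; log2 fold change 2.25, SE 0.16, adjusted p = 9.99e-08). MKI67 had 5743 reads over the 3 DMSO libraries and 2 over the 3 KPT libraries, a ratio of 2872 (95% counting interval 795 to 23720). PTGS2, the inducible cyclooxygenase, went from 57.2 ± 3.68 to 1397 ± 102 RPKM (4.59, SE 0.09, adjusted p = 4.14e-12).

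All 20 mitosis genes fell, as did all 20 adjusted over the list alone (median -3.40, adjusted p = 1.19e-14, and adjusted p = 0.0481 with an estimated correlation). With MKI67, BUB1B and CENPA, which had 3 or fewer reads in the KPT libraries, set at bounds of their read ratios, the median was -3.85. Read ratios carry no pseudocount, unlike the other members, so this median mixes scales and is not a bound on -3.40. CCNB1, cyclin B1, went from 41.5 ± 9.96 to 0.134 ± 0.108 RPKM, and KIF20A, TOP2A, CDCA3 and AURKB changed by -5.01, -4.76, -4.69 and -4.68. S phase genes fell in 16 of 18 members, a count of 16 also adjusted over the list alone (median -1.52, adjusted p = 8.66e-06, and adjusted p = 0.438 with an estimated correlation). UHRF1, a replication-linked epigenetic factor, had 3371 reads with DMSO and 3 with KPT (ratio 1124, 95% interval 384 to 5452), and PCLAF, a PCNA-binding factor, 3349 and 1 (ratio 3349, 601 to 132336). PCNA, a p53 target as well as a replication gene, rose instead, from 59.3 ± 8.95 to 126.5 ± 2.52 RPKM.

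Targets of p53 rose in 17 of 23 members and fell in 4, the same adjusted over the list alone (median 1.01, adjusted p = 4.93e-06, and adjusted p = 0.0481 with an estimated correlation). FAS, a death receptor, went from 8.54 ± 0.954 to 140.9 ± 8.99 RPKM and PHLDA3 rose by 2.05, while SESN1 fell by 0.92. NF-kB and cytokine genes rose in 16 of 18 members and fell in 1 (IRF1, -1.21), again the same adjusted over the list alone (median 1.63, adjusted p = 8.49e-07, and adjusted p = 0.0481 with an estimated correlation). The chemokine CXCL8 went from 1.89 ± 0.490 to 80.6 ± 9.57 RPKM. Matrix proteolysis genes rose in 13 of 19 members and fell in 3, also adjusted over the list alone (adjusted p = 0.00263, and adjusted p = 0.252 with an estimated correlation). MMP1 went from 8.26 ± 1.92 to 582.7 ± 16.1 RPKM, ADAMTS1 rose by 3.37, and ADAMTS9 and PLAU fell by 2.69 and 1.92.

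Contractile and activated-cell genes fell in 15 of 18 members with POSTN the 1 that rose, and likewise adjusted over the list alone (median -1.35, adjusted p = 1.06e-06, and adjusted p = 0.0481 with an estimated correlation). ACTA2 went from 8571 ± 1149 to 2278 ± 242 RPKM, CNN1, calponin, from 384.0 ± 10.96 to 62.3 ± 10.5, and POSTN rose from 1068 ± 130 to 2872 ± 210. Collagen and cross-linking genes fell in 18 of 26 and rose in 3, the same adjusted over the list alone (median -0.76, adjusted p = 4.93e-06, and adjusted p = 0.218 with an estimated correlation), with FBLN2 and LOX changed by -2.05 and -1.30. Cytoplasmic ribosomal proteins fell in 34 of 35 members, and adjusted over the list alone 34 fell and 1 rose (median -0.70, adjusted p = 2.38e-12, and adjusted p = 0.396 with an estimated correlation). RPL3 went from 1615 ± 71.6 to 717 ± 56.5 RPKM and RPL12 from 1393 ± 158 to 503 ± 24.7, in a family whose reads can be shared with pseudogenes.

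Autophagy and lysosome genes rose in 12 of 20 and fell in 3, also adjusted over the list alone (adjusted p = 0.00301, and adjusted p = 0.396 with an estimated correlation). CTSL, a lysosomal protease, went from 297.7 ± 136 to 12231 ± 622 RPKM. Glycolysis genes rose in 12 of 19 and fell in none (0), the same adjusted over the list alone (median 0.37, adjusted p = 0.00405, and adjusted p = 0.619 with an estimated correlation), with PGK1 and LDHA up by 0.63 and 0.53. Nuclear-encoded respiratory chain genes rose in 19 of 36 and fell in 2, also adjusted over the list alone (median 0.20, adjusted p = 0.0282, and adjusted p = 0.722 with an estimated correlation), a call lost in 5 of 19 alternatives. These were quantile normalization (adjusted p = 0.0867), library quality weights (0.0797) and leaving out Stage 3+DMSO replicate 1 (0.0792), Stage 3+KPT replicate 2 (0.0964) or replicate 1 of every group (0.0782). Nuclear transport genes went both ways, with 11 of 30 higher and 11 lower, and did not pass (adjusted p = 0.894).

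Osteogenic genes did not pass as a list either (adjusted p = 0.528), with 3 of 13 higher and 6 lower, 3 and 6 also adjusted over the list alone. RUNX2 rose from 8.88 ± 1.15 to 33.1 ± 3.40 RPKM (1.79, SE 0.10, adjusted p = 7.30e-09), above its level at Stage 1. CEBPB, a transcription factor of inflammation, rose from 108.3 ± 13.0 to 261.6 ± 22.8, SOX9 by 1.01 and MGP by 0.32. BGLAP had 25 and 16 reads and did not pass (adjusted p = 0.440). SPP1 did not pass with all libraries (-0.27, adjusted p = 0.487), and without Stage 3+DMSO replicate 1 it was lower with KPT by a log2 fold change of -0.81 (adjusted p = 8.30e-05).

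AREG, a ligand of the EGF receptor, showed the largest rise, from 7.01 ± 3.99 to 1194 ± 75.7 RPKM (7.33, SE 0.23), with DIO2 (7.30), HSD3B1, of steroid synthesis (5.86), CHI3L2 (5.58), CTSL (5.47), SUSD4 (5.37) and the natriuretic peptide gene NPPB (5.32). Among the largest falls outside the cell cycle were CTHRC1, a collagen-associated secreted protein, from 243.3 ± 8.61 to 6.93 ± 0.400 RPKM (-4.95), and PSAT1, from 599.7 ± 84.5 to 18.7 ± 1.24 (-4.92). In total 7831 genes changed, 3985 higher and 3846 lower with KPT, of which 802 and 1075 by at least 2-fold. Groups did not overlap for 65.2% of genes (10% by chance). The last exon of a gene held more reads relative to the first with KPT (0.467 ± 0.050) than with DMSO (0.271 ± 0.012), a measure of RNA quality or transcript shape that moved with the treatment and hence with every gene group above (exact permutation test, two-sided p = 0.1, the smallest possible).

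**Figure D3:**
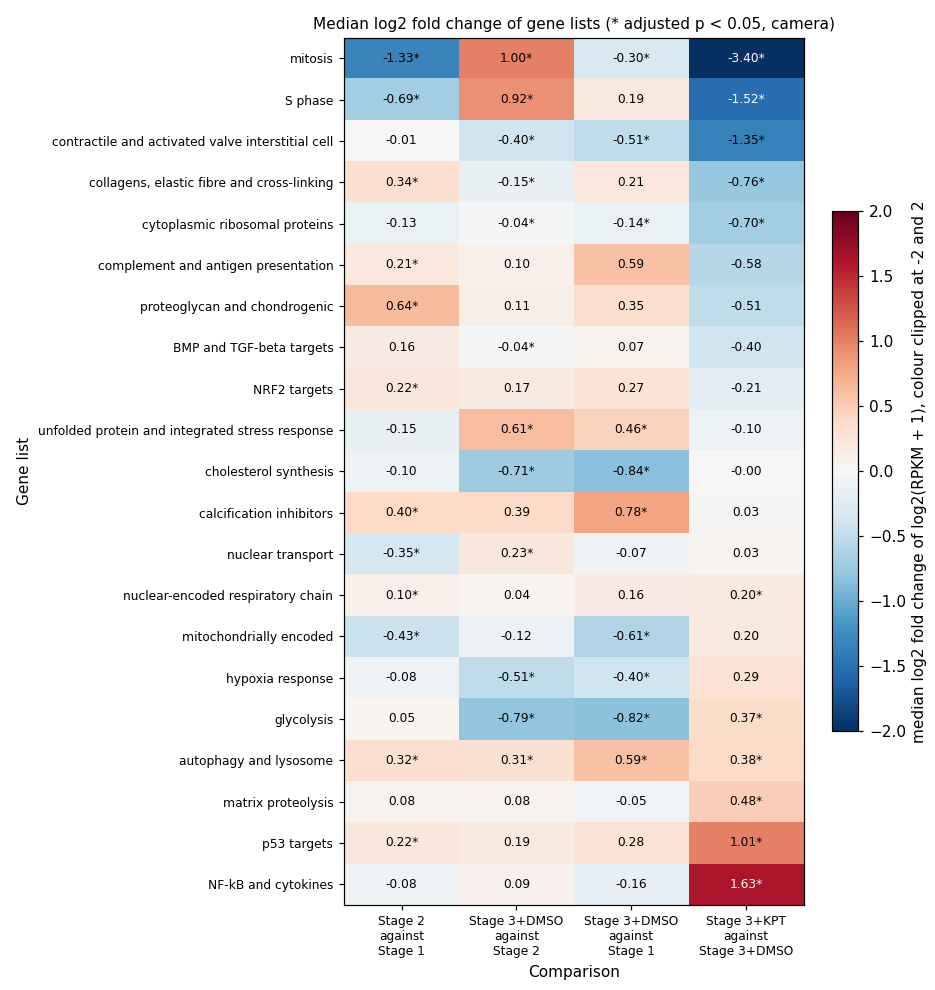
Median log2 fold change of log2(RPKM + 1) over the tested members of 21 gene lists in the 4 comparisons. The lists shown passed a camera adjusted p of 0.05, at the preset correlation of 0.01, in at least 1 comparison. An asterisk marks each such value, and most of these did not pass with the estimated correlation. Mitosis ranges from -3.40 with KPT to 1.00 from Stage 2 to Stage 3+DMSO, where median-ratio rescaling lowers values by about 0.16, and NF-kB and cytokine genes reach 1.63 with KPT.

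The lists that passed in none of the 4 comparisons were osteogenic genes, heat shock, Notch, Wnt, interferon response and endothelial markers. Adjusted p values for Stage 2 against Stage 1, Stage 3+DMSO against Stage 2, Stage 3+DMSO against Stage 1 and KPT against DMSO were 0.562, 0.841, 0.721 and 0.894 for heat shock, 0.332, 0.699, 0.357 and 0.657 for Notch, 0.0609, 0.205, 0.546 and 0.797 for Wnt and 0.813, 0.699, 0.446 and 0.651 for the interferon response. All 19 tested interferon genes were highest in Stage 3+DMSO replicate 1. MX1, an antiviral GTPase, was at 247.4 RPKM there, at 32.5 and 34.2 in the other Stage 3+DMSO libraries and at 71.0 or less in the rest. IFI44L was at 96.9 RPKM in that library, at 70.5 to 79.6 with KPT and at 30.02 or less elsewhere. With fry, which asks whether a list moved at all rather than more than other genes, 75 of the 108 list results passed against 45 with camera, and 41 passed both in the same direction. The 4 that passed camera alone were nuclear-encoded respiratory chain and complement genes at Stage 2 (fry adjusted p = 0.106 and 0.111) and ribosomal proteins in Stage 3+DMSO against Stage 2 and Stage 1 (0.796 and 0.0841). Fry takes up any shift of all genes from the scaling. Osteogenic genes passed fry, as higher, at Stage 2 (adjusted p = 7.69e-04) and in Stage 3+DMSO against Stage 1 (4.37e-05), and still after median-ratio rescaling (1.35e-04 and 1.55e-04). In Stage 3+DMSO against Stage 2 they were higher by fry as deposited (0.0466) but not after rescaling (0.357, as lower) or quantile normalization (0.652), where 0 members were higher and 2 lower, against 4 and 2 as deposited. Notch genes were higher by fry in all 4 comparisons as deposited, but from Stage 2 to Stage 3+DMSO not after rescaling (0.349). Of the 10 Notch members, those called higher and lower were 2 and 1 for Stage 2 against Stage 1. They were 4 and 1 for Stage 3+DMSO against Stage 2 and 5 and 2 against Stage 1. With KPT they were 4 and 4 (median 0.10), so the called members went both ways there. Without Stage 3+DMSO replicate 1, 5608 genes changed from Stage 2 to Stage 3+DMSO and 7565 between KPT and DMSO.

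KPT was also set against the stage changes, to ask whether it moved stage genes back. The 2127 genes that were higher at Stage 2 than at Stage 1 had a median log2 fold change with KPT of -0.09, and 55.8% of them moved in the opposite direction. That median was -0.01 without Stage 2 replicate 1 (-0.0124) and with library quality weights (-0.0149), and -0.02 without replicate 1 of every group. The 3181 genes that were lower at Stage 2 had a median of 0.00 (0.00108), with 50.2% opposite. Neither set passed camera (p = 0.110 and 0.284, or 0.221 and 0.284 adjusted over the 2 sets; p = 0.413 and 0.436 with an estimated correlation), and these comparisons share no library. Both sets passed fry, which asks whether a set moved at all, and both as lower with KPT (fry adjusted p = 9.29e-04 and 3.81e-05, mean log2 fold changes -0.12 and -0.12). Within them MKI67 and AURKB fell at Stage 2 and fell with KPT, while MMP1 and DIO2 fell at Stage 2 and rose with KPT.

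Of the 5755 genes changed from Stage 2 to Stage 3+DMSO, 52.4% moved in the opposite direction with KPT, from 51.2% to 53.2% over the 3 KPT libraries. PSAT1, TOP2A and AURKB rose and then fell with KPT, LDHA fell and then rose, and ACTA2 fell in both. Both comparisons use the same 3 DMSO libraries, and in 100 simulations in which KPT changed nothing the opposite share was 56.7% on average. That is not the share expected of unrelated changes, since 7831 genes differed between KPT and DMSO and their signs rest less on noise. Among 3800 genes called in both, 2041 moved in opposite directions and 1759 in the same. The rise-then-fall genes numbered 1547, where independent lists would share 1270, and the rise-rise genes 1251 (1316). The fall-then-rise genes numbered 494 (442) and the fall-fall genes 508 (426), and independent lists are no exact guide for comparisons that share libraries. The covariance of the log2 fold changes across genes, which are not independent replicates, was -0.0678 against a simulated -0.0116, with a Pearson correlation of -0.177. All simulations here drew noise independently for each gene, with the same spread in every library. Their values and ranges may therefore not hold for the real libraries. The opposite share depends on the scaling. A further 100 simulations without a KPT change gave 56.9% (55.2% to 58.8%) as deposited, above the observed 52.4%. After median-ratio rescaling the share was 54.1%, against 57.4% (56.1% to 59.1%) in simulations on that scale. After quantile normalization it was 57.1%, against 57.5% (55.7% to 59.5%) in simulations on that scale. The 3 DMSO libraries were also split between the comparisons in the 6 ways that leave none in both, which was chosen after seeing the data. The opposite share was then 51.8% on average (48.4% to 53.3%), where unrelated changes would give 49.3%, and the covariance was -0.0500 (-0.0605 to -0.0344). After quantile normalization the split gave 55.1% (52.2% to 57.0%) and unrelated changes 49.99%.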

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

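The counts of splits, the test of library scaling for ribosomal protein genes and the test of a mixture of libraries were chosen after the results they bear on had been seen. No preset criterion for a closer look was applied to single values, since groups of 3 are too small for a test of outlying samples. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In fits of the 2 groups alone, 1 of the 10 splits, the real one, gave as many genes in each comparison. The real split called 5166 genes for Stage 2 against Stage 1 (highest other split 1), 4717 for Stage 3+DMSO against Stage 2 (1), 6213 for Stage 3+DMSO against Stage 1 (0) and 7609 for KPT against DMSO (0).

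Interferon response genes were high in Stage 3+DMSO replicate 1, where 16 of 19 tested genes exceeded the mean of replicates 2 and 3 by more than 2-fold (median log2 ratio 2.76). IFIT1 was at 63.6 RPKM there against 3.73 and 4.45, and RSAD2 at 25.7 against 0.247 and 1.05. A mixture with another of these libraries is argued against, since all 19 genes were higher there than in each of the other 11. An exchange of labels would leave 1 library highest all the same. An exchange with another group is argued against by the second principal component. That library scored 36.3 on it, beside 34.1 and 33.4 in replicates 2 and 3, and no library of another group exceeded 1.10. An exchange within Stage 3+DMSO stays open. Leukocytes in that culture are argued against too, since the 4 detected leukocyte markers had a median log2 ratio of 0.0362 (from -0.94 to 0.27), PTPRC and TYROBP had 0 reads and LAPTM5 3. An interferon exposure of that culture may account for it, but the design names nothing that would test this, and SPP1, which was low in the same library, makes its later-stage rise depend on that library.

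Cytoplasmic ribosomal protein genes fell with KPT in 34 of 35 members (median log2 fold change -0.70). Gene length bias is argued against, since 0 of 10000 lists matched on exon length and mean expression had a median as low (their lowest was -0.49). These lists were drawn from the 50 nearest genes of each member, and how close those were was not checked, which limits this test. Across all tested genes exon length and the KPT log2 fold change had a Spearman correlation of 0.0261. A scaling error of the libraries is argued against as well, since the list lay at -0.7192 relative to the median of all tested genes and at -0.72 after median-ratio rescaling. Reads shared with ribosomal pseudogenes and a difference in RNA quality were not tested and stay open. With those open, an effect of KPT on these transcripts is a hypothesis only.

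More genes were higher than lower in Stage 3+DMSO against Stage 2 (74.9% of the called genes). A candidate explanation is that a few abundant genes took a smaller share of the reads, and the 100 most abundant genes held 35.9 ± 0.737% of gene reads at Stage 2 and 32.1 ± 0.310% in Stage 3+DMSO (SD, n = 3). With library totals that leave these genes out, 63.6% of 5287 called genes were higher, between the range fixed in advance for this explanation and the bound fixed against it. Other numbers of genes, tried after seeing that value, gave 69.6% without 10 genes, 67.2% without 30, 59.5% without 300, 54.6% without 1000 and 46.6% without 3000. The share thus depends on how many genes are left out, so this explanation stays open, as does a change in total RNA, which RPKM values do not show. The difference in stage and solvent stays open as an untested biological explanation.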

How the results depend on the processing

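The limma-voom fit, the minimum of 10 recovered reads and leaving out replicate 1 of every group were chosen after seeing the data. Counts of changed genes stayed within 1.5 times the main count in every alternative, with ranges of 4332 to 7273 (Stage 2 against Stage 1), 4717 to 7089 (Stage 3+DMSO against Stage 2), 5300 to 7017 (Stage 3+DMSO against Stage 1) and 6894 to 8134 (KPT). Limma-voom on recovered reads called 5394, 5951, 6356 and 8101. Replicate numbers did not clearly pair the libraries. Deviations of same-numbered libraries correlated from -0.131 to 0.0748, and 3 of 12 libraries correlated best with their own number. Between Stage 3+DMSO and Stage 3+KPT the same-numbered values were 0.0334 to 0.0748 and the others -0.0809 to 0.0322. The same order held between Stage 1 and Stage 3+DMSO. Between Stage 2 and Stage 3+KPT the same-numbered values were -0.131 to 0.0496. A weak pairing of some groups thus stays open. A fit with the replicate number as a block called 5133, 5641, 6078 and 7725 genes. List tests in all alternatives kept the preset inter-gene correlation of 0.01. With the estimated correlation most list calls of the main fit did not pass, among them every call of glycolysis, S phase and ribosomal proteins. With KPT those that still passed were mitosis, contractile genes, p53 targets and NF-kB genes. Of 2048 list values under alternatives 1984 kept their side of the threshold, 21 were weaker, 41 newly past it and 2 reversed, and of 4022 values of named genes 3935, 69, 17 and 1. Direction was compared only for values past the threshold in at least 1 of the settings, and among those past it in neither, 58 list medians and 3 gene values changed sign. List reversals are by the direction of the camera test. The reversals were ribosomal proteins from Stage 2 to Stage 3+DMSO (adjusted p = 0.986, with a median of -0.00543 that kept its sign) and KDM3A (-0.00635, adjusted p = 0.954), both under quantile normalization, and the interferon list with KPT without replicate 1 of every group (0.318, adjusted p = 0.0427). Without Stage 3+DMSO replicate 1 alone that list did not pass (0.290, adjusted p = 0.0862). The cause of the reversals was not tested.

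The KPT shift of the genes higher at Stage 2 passed the threshold of camera before adjustment in 3 alternatives, but in none of these adjusted over the 2 gene sets. Those were no filter (-0.0938, camera adjusted p = 0.0764), the fit of the compared groups alone (-0.114, adjusted p = 0.0733) and leaving out Stage 2 replicate 3 (-0.121, adjusted p = 0.0721). The cause was not tested. When libraries were left out the shift ranged from -0.121 to -0.0124. The opposite share of genes changed from Stage 2 to Stage 3+DMSO, with an SD of 1.13 between KPT libraries, moved to 54.1% without a filter, 50.7% at a minimum RPKM of 5, 54.1% after median-ratio rescaling, 57.1% after quantile normalization, 54.1% in the 2-group fit and 56.4% without replicate 1 of every group, and from 51.2% to 54.98% when 1 library was left out. The cause was not tested. The shift of genes lower at Stage 2 kept its side of the threshold throughout, but its median changed sign in 14 of 25 alternatives. Where the sign of a list's median, mean and test differed, which was so for 23 of 108 list results, the list had not passed. Depth limits genes with few reads: 3 reads on a gene of 2000 exonic bases are 0.0724 to 0.114 RPKM at Stage 1.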

Other observations

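The 3 gene set tests below were prompted by genes seen in these data and are not adjusted. They were fixed before the values of their members were seen, apart from TXNIP and SESN3. The counts for mitochondrial ribosomal proteins and for successive stage steps were chosen after the results were seen. Many genes moved one way from Stage 1 to Stage 2 and the other way from Stage 2 to Stage 3+DMSO. Of 5308 genes changed at the first step 67.3% moved in the opposite direction at the next, against 57.4% (at most 58.7%) in 100 simulations in which the second step changed nothing but shared the Stage 2 libraries. Those simulations do not give the share expected of unrelated changes, since the second step changed 5755 genes. They also drew noise independently for each gene with the same spread in every library, so their range may be too narrow. Genes that fell and then rose numbered 1658, where independent lists would share 1051, and those that rose and then fell 507, where they would share 236. These counts depend on the scaling. After median-ratio rescaling, chosen after seeing the data, 1013 fell and then rose (541 if independent), 890 rose and then fell (503), and 66.0% of 5272 genes moved in the opposite direction, against 57.25% in simulations on that scale. With the 3 Stage 2 libraries split between the steps in the 6 ways that leave none in both, also chosen after seeing the data, the share was 64.4% (58.4% to 68.1%) as deposited, where unrelated changes would give 53.2%. As deposited, the covariance was -0.0607 against a simulated -0.0117. Mitosis genes followed this course, and MGP, GAS6 and PLXDC1 instead rose at both steps, as did 565 genes, where 703 would be shared by independent lists.

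While cytoplasmic ribosomal protein genes fell with KPT, 31 of 65 mitochondrial ribosomal protein genes rose and 9 fell (median 0.20). Of the C/EBP genes, too few for a list test, CEBPD averaged 351.7 RPKM with DMSO and 679.6 with KPT, CEBPZ 32.8 and 56.6, and CEBPG 31.9 and 17.9. The cardiomyocyte-marker NPPB averaged 0.242 RPKM with DMSO and 48.95 with KPT, while TNNI3 was at 0.909 and 1.10 and PLN at 2.28 and 3.27. Of the leukocyte markers CD14 averaged 12.1 and 10.7 RPKM, CD68 2.53 and 2.91, SPI1 0.568 and 0.645 and ITGB2 0.641 and 1.76. CIDEC, an adipocyte gene, was at 1.63 and 1.17, and the sex-linked EIF1AY at 0.929 and 0.737.

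AREG, DIO2 and PTGS2 are known to respond to cAMP, which led to the hypothesis that genes regulated by the transcription factor CREB rise with KPT as a set. A list that leaves out these 3 genes had 11 tested members, of which 10 rose and 0 fell (median 1.6783, camera p = 1.15e-05, and p = 0.109 with an estimated correlation). NR4A2 rose by 3.27 (SE 0.28), PDE4B by 2.76, PDE4D by 2.26 and RGS2 by 2.19, while FOS did not pass (0.24, adjusted p = 0.104). CREB activity may thus be part of the response, but these genes also respond to other signals, and the call does not hold with the estimated correlation.

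Factors of the FOXO family are known cargo of XPO1, and a FOXO-regulated list was tested as a second hypothesis. With KPT 7 of 11 members rose and 1 fell (median 0.52139, camera p = 0.0269, and p = 0.221 with an estimated correlation), with KLF9, CCNG2 and BCL6 up by 1.77, 1.47 and 1.25 and PIK3IP1 changed by -1.35. The median passed the bound fixed in advance by little, so this may be no more than a weak shift. The rise of TXNIP at Stage 2 led to the same test for Stage 2 against Stage 1 without TXNIP. Of its members there, 10 in number, 4 rose and 2 fell. The median was 0.090911 with a camera p = 0.117 (p = 0.355 with an estimated correlation), which leaves that hypothesis undecided.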
